A study of Mus musculus with 2 samples.

How the data were processed

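Gene expression was measured on 2 two-colour spotted microarrays of mouse tendon cells. One array held cells sheared for 6 h and the other cells sheared for 12 h. Per the labels, channel 1 (Cy3) of each array carried RNA of control cells of the same time point and channel 2 (Cy5) carried RNA of sheared cells. The shear setting of 50 rpm is given in the label of the 12 h sample, and pooling of cells is given in the labels of the 6 h sample. There was 1 array per time point, the dyes were not swapped, and no sample was left out. No p-value can therefore be given for any gene or list, and the number of arrays limits the precision of each value.

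The deposited table holds a log ratio per spot for each array, 42624 spots in all. How the authors normalized these values is not given in the sources used here, and neither are the scanner, the background correction or a spot filter. The deposited values were taken as log2 ratios: they run from -8.48 to 5.48, which excludes linear ratios, and such a range on a log10 scale would exceed what a 16-bit scanner can record. The base of 2 is nevertheless an assumption, as is the direction, which is likely sheared over control. That direction rests on the labels placing the sheared RNA in Cy5 and on the Stanford Microarray Database, to which the labels link the array images, storing red over green. If the ratio ran the other way, every higher value below would be a lower one and the reverse. The deposited log2 ratios were not centred on 0. Their median was -0.323 at 6 h, with 39776 spots measured and 2848 missing, and -0.479 at 12 h, with 41717 spots measured and 907 missing. Spot intensities were not used here, so neither the brightness of a spot nor an intensity-dependent dye trend can be checked, and the depth of the measurement is unknown.

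From these values, each array was centred on its median over all spots. Spots were named through GEO's platform annotation, with symbols looked up by gene ID in the RefSeq gene table of GRCm38.p6. Of the 42624 spots, 21703 carried exactly 1 gene symbol, 1122 carried several and 19799 had no gene in the annotation. All gene IDs were found in the gene table for 22690 annotated spots, and 2 symbols were updated. A gene's value was the median of its probes with exactly 1 symbol, which gave 10348 genes at 6 h, 10733 at 12 h and 10288 on both arrays. The only error estimate within an array is the SD between different probes of the same gene. Pooled over 5396 genes it was 0.738 log2 at 6 h, and pooled over 5579 genes it was 0.855 at 12 h. This spread covers clones and spots, not cultures, and includes clones assigned to a wrong gene.

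The comparisons were fixed before the data were examined. Genes at least 2-fold higher or lower were counted on each array. The 2 arrays were compared by the correlation across genes and by the overlap of these genes. For 31 gene lists (22 pathway lists and 9 lists of tendon and other cell type markers), the median of the members was placed among the medians of 10000 random lists of the same size, matched on 1, 2, or 3 or more probes per gene. They could not be matched on expression level, because the table holds ratios only. A list was said to stand apart below percentile 2.5 or above percentile 97.5, and a member was counted as higher or lower from 1.5-fold. The percentiles describe these arrays and are no test of the conditions. Single genes were named by a rule that, except for the members of lists, required a value on both arrays and all probes of a gene on the array in question on one side of 0 and passed over unnamed transcripts. It took the 6 highest and 6 lowest genes of each array past 2-fold, then the 4 highest and 4 lowest with 2 or more probes past 1.5-fold. It also took the 8 highest and 8 lowest on both arrays by the smaller of the 2 values, the 4 with the largest difference between times in each direction among genes past 1.5-fold on opposite sides, and the 3 members of each list with the largest mean absolute log2, whose probes can lie on both sides of 0, as those of Id3 did. Any other gene is named as chosen after its values were seen. A result on 1 further gene family is not reported here.

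The alternatives tried were the values as deposited without centring, the mean of a gene's probes, only genes with 2 or more probes, only genes on both arrays, probes with several symbols kept under each symbol, both arrays scaled to one median absolute deviation, thresholds of 1.5-fold and 3-fold, and the Spearman correlation. Centring of each of the 48 print blocks, taken as 900 consecutive spot numbers, was added after the data were seen. The list percentile was tested on simulated data, in which gene values were permuted and 400 lists of 20 genes were shifted by a known amount. With no shift, 6.75% of the lists stood apart at 6 h and 3.75% at 12 h. With a shift of 0.5 log2 the shares were 56.8% and 43.0%, and with a shift of 1.0 log2 they were 99.0% and 95.0%. The counts were also tested on simulated data in which genes differed only by the scatter between probes of a gene, except for 200 genes shifted by 1.5 log2. Of these, 86.9% passed 2-fold at 6 h and 83.0% at 12 h. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots used matplotlib 3.10.9.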

Results

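The study asked how mechanical shear affects flexor tendon cells. Tenocytes, the fibroblast-like cells of tendon, were sheared for 6 h or 12 h, and their RNA was hybridised against RNA of control cells of the same time point on spotted two-colour arrays. The data are 2 arrays, 1 per time point, with 39776 spots measured at 6 h and 41717 at 12 h. These gave values for 10348 and 10733 named genes, and 10288 genes had a value on both arrays. All values were taken as log2 ratios of sheared over control after centring each array on its median; the base is assumed and the direction is likely, from the dyes in the labels and the red-over-green convention of the image database. Without replicate arrays no difference could be tested, so higher and lower describe these arrays. The pooled SD between different probes of a gene, 0.738 log2 at 6 h and 0.855 at 12 h, was the only available error. The medians subtracted were -0.323 at 6 h and -0.479 at 12 h, so every value lies lower by that amount without centring.

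Genes of the metal, oxidative and acute stress responses were among those that read highest in the sheared cells at 6 h. The metallothioneins Mt1 and Mt2, which bind heavy metals, stood at log2 4.92 (probe SD 2.03, 4 probes) and 4.25 (probe SD 0.19, 2 probes), and these near-identical transcripts can share signal. Hmox1, which degrades heme, stood at 4.01 (probe SD 0.37, 2 probes), or 16.1-fold higher. Hbegf, a ligand of the EGF receptor, stood at 3.52 (probe SD 0.15, 2 probes). Immediate early genes, the transcription factors and regulators induced first after a stimulus, had a median of 1.47 over 19 measured genes, a 2.77-fold higher level. Of these, 14 were at least 1.5-fold higher and none was 1.5-fold lower. Lower values were found in TGF-beta and BMP signalling, with a median of -0.55 over 26 genes.

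The stress lists of the 6 h array held many members in one direction. In the immediate early list, Gadd45b stood at 2.23, Atf3 at 2.54 and Fosl1 at 2.63, and the 4 probes of Atf3 had an SD of 1.94. The list lay at percentile 100 among random lists. Of 23 shear and oxidative stress genes, 13 were at least 1.5-fold higher and 1 lower, with a median of 0.67 and a percentile of 100. Heat shock proteins and chaperones, which keep other proteins folded, had a median of 1.20 (2.30-fold) over 21 genes, of which 19 were at least 1.5-fold higher and none lower. Among them, Hspa1b stood at 2.10 (probe SD 0.09), the small heat shock protein Cryab at 1.24 (probe SD 0.07) and Hsp90aa1 at 1.55 (probe SD 0.69, 12 probes). Hspa1b has a near-identical copy, Hspa1a, so the 2 cannot be told apart by hybridisation. In the unfolded protein response, 6 of 20 genes were at least 1.5-fold higher and 1 lower, with a median of 0.43 at percentile 97.8. That percentile fell inside 95% of random lists with the mean of probes (96.1), with 2 or more probes per gene (97.1) and with probes of several symbols kept (96.0). Its transcription factors Ddit3 and Atf4 stood at 1.53 (probe SD 0.21) and 1.36 (probe SD 0.12), while the sensor Atf6 stood at -1.65 on 1 probe.

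Genes of protein synthesis, protein breakdown and energy supply were also higher at 6 h. All 47 ribosomal protein genes were at least 1.5-fold higher, with a median of 1.17 (2.25-fold) and quartiles of 1.03 and 1.28. For oxidative phosphorylation 33 of 36 genes were at least 1.5-fold higher and none lower, with a median of 0.94. For the proteasome this held for 25 of 28 genes, with a median of 1.02. Glycolysis and hypoxia response genes had a median of 0.37 over 26 genes, with 8 higher, 2 lower and a percentile of 98.9. Among them the angiogenic factor Vegfa stood at 1.41 (probe SD 0.13), lactate dehydrogenase Ldha at 1.24 (probe SD 0.24) and the phosphofructokinase Pfkm at -1.12 on 1 probe. Beside these lists, 28 abundant short transcripts, such as ferritin and thymosin transcripts, had a median of 0.72 on this array. They lie outside the lists for ribosomal proteins, respiration, the proteasome and chaperones. They include Gapdh and Mif of the glycolysis list and B2m of the interferon list. The medians of shear and oxidative stress (0.67), unfolded protein response (0.43) and glycolysis genes were not above 0.72. Those of heat shock genes (1.20) and immediate early genes (1.47) were. A set of 23 abundant long transcripts of fibroblasts had a median of -0.34, and both sets were drawn up after the lists had been seen. Neither transcript length nor abundance was measured here. Most of the long transcripts belong to the collagen, matrix, integrin or YAP and SRF lists.

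Secreted signals were mixed at 6 h. Of 22 inflammatory cytokine and chemokine genes, 8 were at least 1.5-fold higher and 5 lower. The median was 0.26 at percentile 97.2, and it turned to -0.06 without centring and was 0.14 at percentile 69.8 over the 11 genes with 2 or more probes. The monocyte attractant Ccl7 stood at 2.32, while the growth factor Csf2 stood at -3.30, each on 1 probe. Cxcl1, a neutrophil attractant, stood at 2.71 on 1 probe. The interferon response list had a median of 0.32 over 17 genes, with 6 higher and none lower, at percentile 95.1 (99.2 over the 11 genes with 2 or more probes). With probes of several symbols kept the median was 0.17 at percentile 82.2, and it turned negative without centring. Its examples Ifitm1, Irf9 and B2m stood at 1.38 (probe SD 0.26), 0.46 and 1.03 (probe SD 0.13). Of 30 growth factor and receptor genes, 13 were lower and 3 higher, with a median of -0.33 at percentile 6.97, but over the 21 genes with 2 or more probes the median was 0.00 at percentile 37.8. Igfbp5, an IGF-binding protein, stood at -2.43 (probe SD 1.20) and the fibroblast growth factor Fgf7 at -1.61 on 1 probe.

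The matrix and signalling lists were centred near 0 or below at 6 h. In TGF-beta and BMP signalling, 13 of 26 genes were at least 1.5-fold lower and 4 higher, at percentile 1.12 among random lists, or 3.69 with the mean of a gene's probes. The repressor Tgif1 stood at 2.37 on 1 probe, against -1.10 for Id3 (probe SD 1.56, 3 probes) and -1.21 for the accessory receptor Tgfbr3 on 1 probe. Of 20 collagen genes 7 were lower and 1 higher, with a median of -0.34 at percentile 7.74. Col12a1, a fibril-associated collagen, stood at -2.32 (probe SD 0.50), Col6a3 at -0.97 and Col5a1 at -1.10 (probe SD 0.33). The main tendon collagens, chosen after their values were seen, stood at -0.43 for Col1a1 (probe SD 0.22, 4 probes), 0.11 for Col1a2 (probe SD 0.34, 5 probes) and 0.03 for Col3a1 (probe SD 0.51, 5 probes). Collagen processing genes had a median of 0.25 and matrix proteoglycans and glycoproteins 0.04, both turning negative without centring, and metalloproteinases with their inhibitors had a median of -0.02. Fn1, fibronectin, also chosen after its values were seen, stood at -1.16 (probe SD 0.13), Thbs1, thrombospondin 1, at -0.99 (probe SD 0.21) and Mgp, matrix Gla protein, at 0.89 (probe SD 0.12).

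The remaining lists of the 6 h array lay within 95% of random lists, with exceptions under other settings for leukocyte and epithelial markers. The medians were 0.22 for tendon markers and 0.10 for YAP and SRF targets, and both turned negative without centring. They were -0.19 for integrins and focal adhesion, -0.19 for the cell cycle, -0.17 for apoptosis and p53 targets, 0.24 for cholesterol and fatty acid synthesis, which also turned negative without centring, and -0.24 for Wnt signalling. Among their leading members, the integrin Itgb3 stood at -2.48, the mitotic regulator Cdc20 at -3.20 and the Wnt ligand Wnt11 at 2.06, each on 1 probe, while the replication clamp Pcna stood at 2.03 (probe SD 0.32, 6 probes). Wnt11 was the only gene of the Wnt list at least 1.5-fold higher, against 6 lower, among them Dvl1 at -3.415 on 1 probe. Markers of other cell types had medians of -0.56 for leukocytes, -0.53 for endothelium, 0.11 for skeletal muscle, -0.40 for cartilage and bone, -0.48 for adipocytes, -0.51 for erythroid cells, -0.45 for epithelium and 0.02 for neural cells, and the muscle and neural medians turned negative without centring. With 2 or more probes per gene, leukocyte markers lay at percentile 0.70 over 5 genes and epithelial markers at 2.45, and the latter lay at 2.35 with print blocks centred and 0.36 with the mean of probes. For comparison, the median of all genes was -0.11.

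Across the 6 h array, 641 genes were at least 2-fold higher and 1951 at least 2-fold lower, so that 24.7% of them were higher. Without centring the counts were 246 and 2901, and 7.82% were higher. Simulated genes that differed only by the scatter between probes gave 432 higher and 469 lower. Besides the genes above, the rule for the highest values named Cd40lg at 5.30, Fbxl22 at 3.97 and Gnmt at 3.53, each on 1 probe. Among genes with several probes it named Noct at 3.26 (probe SD 1.32), Bcl9 at 2.64 (probe SD 3.29) and Ppp1r15a, a stress-induced phosphatase subunit, at 2.53 (probe SD 1.22). The lowest were Ankrd26 at -6.90, Sbk1 at -6.33, Kprp at -5.97, Lratd2 at -5.91, Dio3 at -5.79 and Fat3 at -5.67, each on 1 probe. Among genes with 2 probes the lowest were Mylk, myosin light chain kinase, at -4.37 (probe SD 1.86), Kbtbd3 at -4.30, Myo5b at -4.03 and Cdyl2 at -3.95. Values resting on 1 probe have no check of their own.

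At 12 h the highest lists were those of protein synthesis and respiration. All 47 ribosomal protein genes were at least 1.5-fold higher, with a median of 2.22 (4.65-fold) and quartiles of 2.07 and 2.43. Examples were Rps29 at 2.71 (probe SD 0.11, 5 probes), Rps18 at 2.55 (probe SD 0.08) and Rpl37 at 2.65 (probe SD 0.74). Oxidative phosphorylation genes had a median of 1.89 (3.71-fold), with 35 of 36 genes higher and none lower. They included Ndufa1 at 2.32 (probe SD 0.73), Cox5b at 2.44 (probe SD 0.52) and Cox8a at 2.02 (probe SD 0.36). Proteasome subunits had a median of 1.45 (2.73-fold), with 24 of 28 higher and none lower, such as Psmb4 at 2.23 (probe SD 0.48), Psmb6 at 2.33 (probe SD 0.01) and Psmb5 at 2.28 (probe SD 0.17). All 3 lists lay at percentile 100. The abundant short transcripts outside these lists had a median of 1.61 on this array and the abundant long ones -0.35. Ribosomal protein transcripts have many processed copies in the genome and can hybridise across probes.

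Stress genes also read high on the 12 h array. The median of each list in this paragraph nevertheless lay below the 1.61 of the abundant short transcripts. The random lists were matched on neither expression level nor transcript length. Mt1 stood at 3.26 (probe SD 1.17), Mt2 at 3.08 (probe SD 0.05) and Hmox1 at 2.78 (probe SD 0.90). Shear and oxidative stress genes had a median of 1.01 (2.02-fold), with 15 of 23 higher and 1 lower. Heat shock proteins and chaperones had a median of 1.20 (2.29-fold), with 20 of 21 higher and none lower, including Hspa1b at 1.98 (probe SD 0.75), Cryab at 2.30 (probe SD 0.18) and Hsp90aa1 at 1.66 (probe SD 0.49). Immediate early genes had a median of 0.73 (1.66-fold) at percentile 99.6, with 11 of 19 higher and 3 lower. The 3 lower members, named after their values were seen, were Egr1 at -1.81, Klf6 at -1.61 (probe SD 1.59) and Nr4a1 at -1.03. Unfolded protein response genes had a median of 0.56 with 9 of 20 higher and 3 lower, at percentile 97.515, on the bound. They fell inside 95% of random lists with the mean of probes (93.3), with 2 or more probes per gene (94.6), with several symbols kept (97.1) and over genes on both arrays (97.4). Ddit3 stood at 1.67 (probe SD 0.30), Atf4 at 1.44 (probe SD 0.12) and Atf6 at -1.96. Glycolysis and hypoxia genes had a median of 0.54 with 12 of 26 higher and 4 lower, including Vegfa at 1.69, Ldha at 1.79 and Pfkm at -2.75.

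Genes that process collagen stood apart at 12 h, while the collagens themselves did not. Collagen processing and crosslinking genes had a median of 0.81 (1.75-fold) over 12 genes, of which 9 were higher and none lower, at percentile 99.3. Loxl2, a crosslinking oxidase, stood at 2.5 on 1 probe, the procollagen protease enhancer Pcolce at 1.48 (probe SD 0.78) and the prolyl hydroxylase subunit P4hb at 0.82 (probe SD 0.26). Over the 7 of these genes with 2 or more probes, the median was 0.82 at percentile 94.1. The abundant short transcripts had a median of 1.61 on this array. The collagens had a median of -0.28 at percentile 19.9, with none of 20 higher and 8 lower, including Col12a1 at -2.64 (probe SD 0.17), Col6a3 at -1.46 and Col5a1 at -1.19 (probe SD 0.49). Col1a1 stood at -0.35 (probe SD 0.53), Col1a2 at -0.05 (probe SD 0.32) and Col3a1 at -0.10 (probe SD 0.48). Matrix proteoglycans and glycoproteins had a median of -0.11, or 0.45 over the 11 genes with 2 or more probes, with 5 of 20 higher and 5 lower, the latter including Fbn2 at -1.27, Thbs1 at -1.56 (probe SD 0.73) and, chosen after its values were seen, Fn1 at -1.26 (probe SD 0.08). Mgp stood at 1.65 (probe SD 0.19). Metalloproteinases and inhibitors had a median of 0.18, which turned negative without centring, with Timp4 at -1.68, Adamts1 at -1.93 and the urokinase receptor Plaur at 0.96 (probe SD 0.43).

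TGF-beta and BMP signalling genes did not stand apart from random lists at 12 h. Their median was -0.54 over 27 genes, of which 13 were at least 1.5-fold lower and 6 higher, at percentile 3.10. With print blocks centred the median was -0.30 at percentile 17.9, and over the 26 genes on both arrays without block centring the percentile was 0.80. Id3 stood at -2.48 (probe SD 2.17), Tgfbr3 at -2.30 and Tgif1 at 1.95. The signalling receptors and a receptor-activated Smad, chosen after their values were seen, stood at -1.69 for Tgfbr1 on 1 probe, -1.40 for Tgfbr2 (probe SD 0.03, 2 probes) and -2.23 for Smad3 (probe SD 0.83, 4 probes). The ligands, chosen in the same way, differed in sign: Tgfb1 stood at 0.88 (probe SD 0.20) and Tgfb2 at -1.73 (probe SD 0.56).

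The other lists of the 12 h array lay within 95% of random lists. Medians were -0.20 for tendon markers (0.25 with 2 or more probes per gene), -0.05 for YAP and SRF targets (0.16 likewise), -0.09 for integrins and focal adhesion, -0.13 for inflammatory genes and 0.11 for the interferon response, the last turning negative without centring. They were -0.22 for the cell cycle, -0.29 for apoptosis and p53 targets, 0.09 for cholesterol and fatty acid synthesis (negative without centring), -0.23 for growth factors and receptors and -0.04 for Wnt signalling. Among the YAP and SRF targets, the matricellular gene Ccn1 stood at -1.86 and Amotl2 at -1.55 (probe SD 0.05), while the smooth muscle gene Cnn1 stood at 1.55. Bcl2l1, an inhibitor of apoptosis, stood at -2.60 on 1 probe. Marker medians were -0.05 for leukocytes, -0.15 for endothelium, 0.08 for skeletal muscle, -0.17 for cartilage and bone, 0.18 for adipocytes, -0.45 for erythroid cells, -0.28 for epithelium and 0.16 for neural cells, and those of muscle, adipocytes and neural cells turned negative without centring. The neural median was -0.19 with the mean of probes. The median of all genes was -0.14.

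Across the 12 h array, 1558 genes were at least 2-fold higher and 2203 lower, so that 41.4% of them were higher. Without centring the counts were 742 and 3763, and 16.5% were higher. Scatter between probes alone gave 654 and 661 in simulated data. The highest were Zfp12 at 3.75, Hbegf at 3.62 (probe SD 0.23), Noxred1 at 3.58, Wdr63 at 3.58, Rabggta at 3.45 (probe SD 0.97) and the mitochondrial sirtuin Sirt4 at 3.44. Zfp12, Noxred1, Wdr63 and Sirt4 rested on 1 probe each. Among genes with several probes, Pgc stood at 3.25 (probe SD 3.48) and Tspan15 at 2.97 (probe SD 2.0). The lowest were Rbms3 at -8.0, Rps6ka5 at -7.09, Frat2 at -5.98, Garem1 at -5.84, Clca3a1 at -5.80 and Cfap45 at -5.73, each on 1 probe. With several probes, the lowest were Tanc1 at -4.68 (probe SD 1.55), Socs7 at -3.91 (probe SD 0.66), Mga at -3.83 (probe SD 1.55) and Setbp1 at -3.81 (2 probes).

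**Figure D1:**
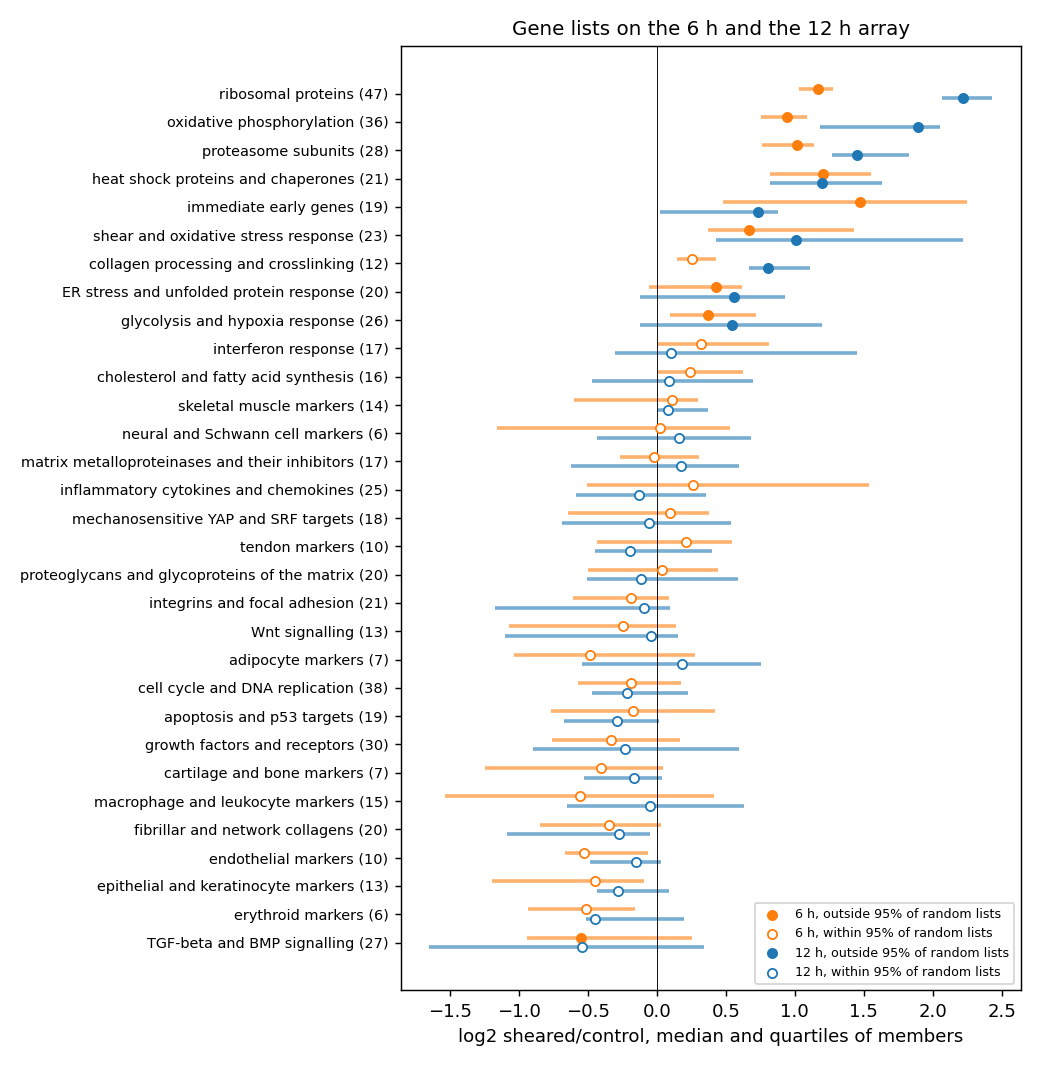
Median (point) and quartiles (line) of the log2 ratio of sheared over control over the members of 31 gene lists, at 6 h (orange) and 12 h (blue), with the number of genes in brackets. Filled points lie outside 95% of 10000 random lists of the same size; ribosomal proteins lie highest at 12 h (2.22) and TGF-beta and BMP signalling is the only filled list below 0, at 6 h.

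The 2 time points were compared gene by gene, and stress genes were among the highest on both arrays. The genes highest on both arrays by the smaller value were Hbegf (3.52 at 6 h and 3.62 at 12 h), Mt1, Mt2, Hmox1, Osgin1 (3.23 and 2.54), an oxidative stress-induced growth inhibitor, and Ppp1r15a (2.53 and 2.49). They were followed by the snoRNA host gene Zfas1 (2.40 and 2.35) and Amd2 (2.24 and 2.45), whose signal cannot be separated from that of its parent gene Amd1. The lowest on both were Garem1 (-4.69 and -5.84), Tmem174 (-5.29 and -4.52), Sdr16c5 (-4.14 and -3.97), Slc46a3 (-3.83 and -4.52), Tanc1 (-3.77 and -4.68), Cdk6 (-3.92 and -3.74), Myo5b (-4.03 and -3.71) and Irs1 (-4.43 and -3.54), the insulin receptor adaptor. Osgin1, Zfas1 and all of these lowest genes except Tanc1 and Myo5b rested on 1 probe per array. Of the 10288 genes on both arrays, 446 were at least 2-fold higher on both and 1008 at least 2-fold lower on both. Independent lists of the same sizes would share 95.4 and 364. The correlation across genes was 0.66 (Pearson) and 0.74 (Spearman), and 80.5% of genes had the same sign. Genes are not independent replicates, and both arrays carry the sheared RNA in the same dye, so that a dye effect would add to this overlap.

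**Figure D2:**
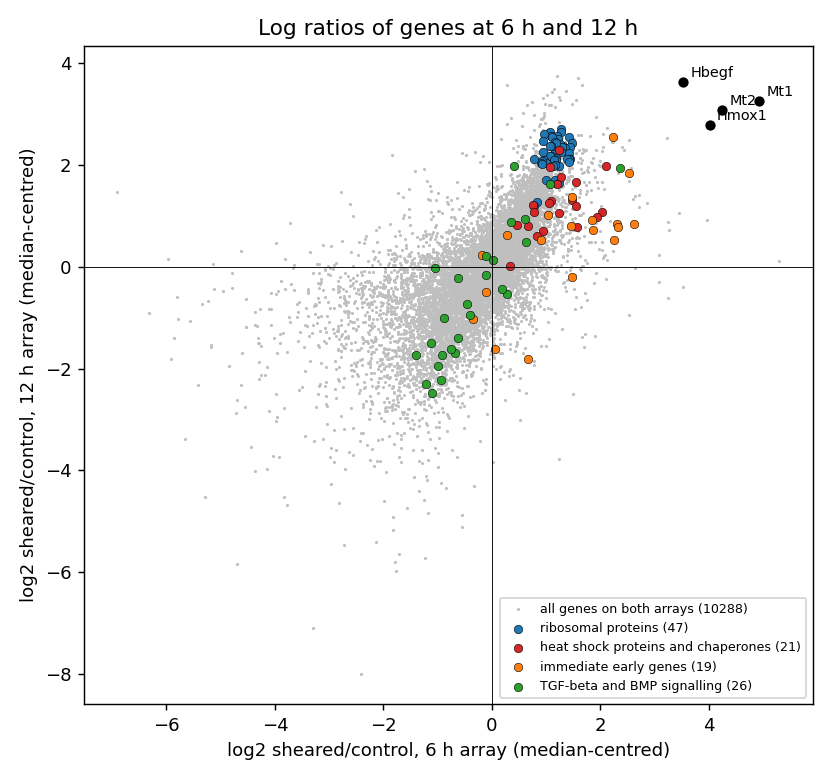
Log2 ratio of sheared over control at 6 h (x axis) and 12 h (y axis) for 10288 genes on both arrays (grey), with 4 gene lists in colour and 4 single genes in black. Ribosomal protein genes (blue) lie higher at 12 h than at 6 h, immediate early genes (orange) mostly lie higher at 6 h, and Mt1, Mt2, Hmox1 and Hbegf lie far above 0 on both axes.

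Several lists lay at different levels at 6 h and 12 h. The ribosomal protein genes were higher at 12 h than at 6 h in 47 of 47 cases, by a median of 1.08 log2. The 28 abundant short transcripts set beside them above had medians of 0.72 at 6 h and 1.61 at 12 h. Oxidative phosphorylation genes were higher at 12 h in 34 of 36 cases, by 0.89, proteasome genes in 25 of 28, by 0.51, and collagen processing genes in 10 of 12, by 0.69. With both arrays scaled to one median absolute deviation these differences were 0.69 for ribosomal proteins, 0.55 for oxidative phosphorylation, 0.21 for the proteasome and 0.60 for collagen processing. Markers of other cell types also differed. The median difference was 0.64 for adipocytes (4 of 6 higher at 12 h), 0.53 for neural cells (5 of 6), 0.44 for leukocytes (11 of 15) and 0.39 for epithelium (11 of 13). With the arrays scaled these were 0.65, 0.47, 0.50 and 0.44, and without centring 0.48, 0.38, 0.28 and 0.23. The remaining differences were smaller: 0.32 for skeletal muscle, 0.29 for endothelium, 0.17 for cartilage and bone and 0.17 for erythroid cells. Immediate early genes ran the other way: 3 of 19 were higher at 12 h, and the median difference was -0.70, or -1.22 with the arrays scaled. Examples were Fosl1, at 2.63 and then 0.83, and, chosen after their values were seen, Myc (2.33 and 0.78, probe SD 0.23 and 0.22), Btg2 (2.26 and 0.52, probe SD 0.29 and 0.35) and Fos (1.87 and 0.73, probe SD 0.30 and 0.53). Heat shock genes differed by a median of 0.11, which turned to -0.26 with the arrays scaled and to -0.05 without centring. In TGF-beta and BMP signalling 8 of 26 genes were higher at 12 h, with a median difference of -0.35, or -0.20 with the arrays scaled and -0.18 with print blocks centred. The array, the pooling stated for the 6 h cells and the time cannot be told apart, and these differences were not tested.

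**Figure D3:**
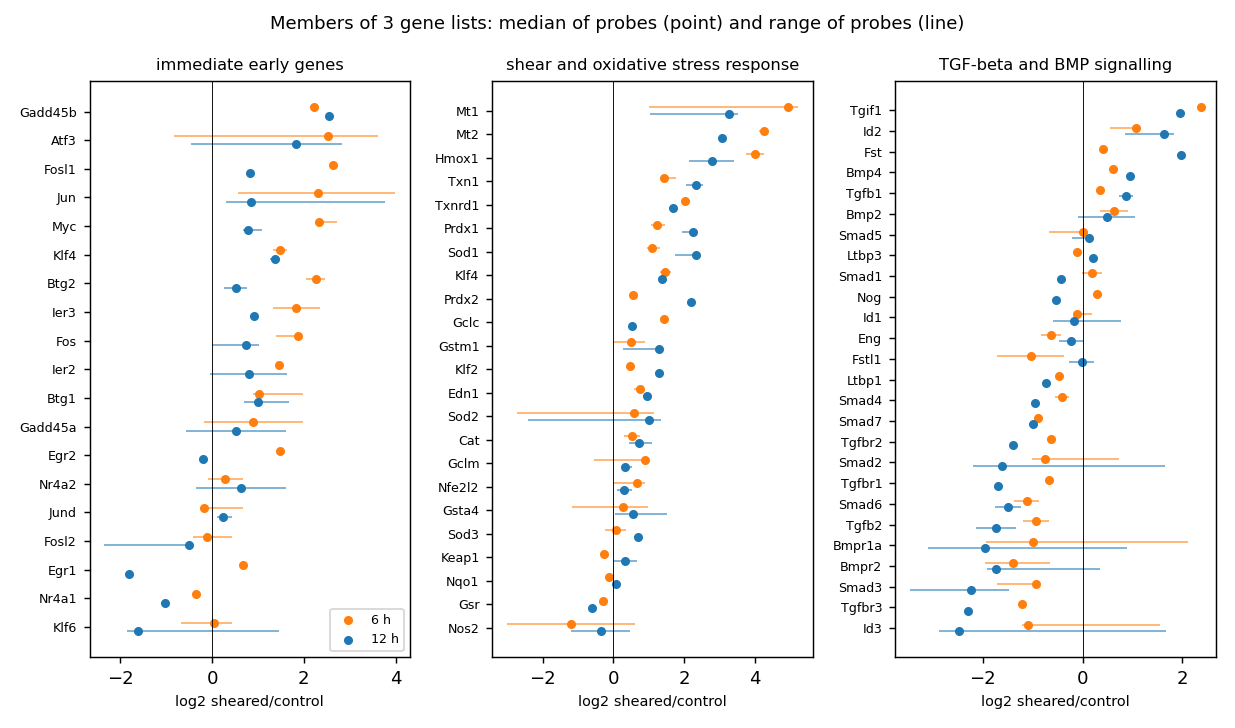
Log2 ratio of sheared over control of each member of 3 gene lists with a value on both arrays, at 6 h (orange) and 12 h (blue); points are the median of a gene's probes and lines their range. Fosl1, Myc and Btg2 lie above 2 at 6 h and below 1 at 12 h, and Mt1, Mt2 and Hmox1 lie highest in the middle panel.

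Some genes lay on opposite sides of 0 at the 2 times. Of the genes with all probes on one side, 94 were past 1.5-fold in opposite directions, 47 each way. The largest differences towards 12 h were those of Ankrd26 (-6.90 and 1.48), Hpdl (-3.73 and 0.86), Sox21 (-1.85 and 2.20) and Zcchc14 (-2.62 and 1.23). The largest towards 6 h were those of Fry (1.24 and -3.78), Fcmr (3.25 and -0.62), Niban1 (2.52 and -0.94) and Nfkbiz (1.70 and -1.58), a regulator of NF-kappa-B. All 8 rested on 1 probe per array.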

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

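The tests on abundant long transcripts and on the scatter of the 12 h array were chosen after the results had been seen, and the others were set down before their values were known. The set of abundant short transcripts was nevertheless drawn up after the results of the gene lists had been seen. Genes past 1.5-fold in opposite directions at 6 h and 12 h were singled out because the only array of one time point read higher and the only array of the other read lower; these differences were not tested. The difference, log2 at 12 h minus log2 at 6 h, was 8.38 for Ankrd26, 4.59 for Hpdl, 4.05 for Sox21, 3.84 for Zcchc14 and 1.46 for Myl1. It was -5.02 for Fry, -3.87 for Fcmr, -3.46 for Niban1, -3.28 for Nfkbiz, -2.49 for Egr1 and -2.41 for Kdr. The 2 probes of Kdr had an SD of 2.62 at 6 h and those of Myl1 an SD of 2.0.

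The first pattern is that ribosomal protein genes stood at 1.17 and 2.22 on the 2 arrays, together with respiration and proteasome genes. Bright spots reading high in Cy5 would raise all abundant transcripts, whereas the 23 abundant long transcripts lay 1.51 (95% bootstrap interval over genes 1.11 to 2.12) and 2.57 (2.22 to 3.44) below the ribosomal proteins. That set was chosen after the results had been seen, and most of its genes belong to the collagen, matrix, integrin or YAP and SRF lists. Its low median can therefore not be told apart from a change in those genes. Spot brightness was not measured here, so the explanation stays open. Short abundant transcripts reading high in the sheared RNA, through RNA length or quality, would raise short transcripts of any function. The 28 short transcripts were also drawn up as a set after the lists had been seen, and their length was not measured here. They lie outside the lists for ribosomal proteins, respiration, the proteasome and chaperones. At 6 h they lay 0.450 (0.209 to 0.626) below the ribosomal proteins, inside the preset bound of 0.5. At 12 h they lay 0.609 (0.272 to 1.1) below. On the 2 arrays, 17 and 24 of them were at least 1.5-fold higher. High readings of short transcripts may thus account for much of the pattern and cannot be told apart from a change in the cells.

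The second pattern is the correlation of 0.66 between the arrays. Effects particular to a single probe were not the whole cause. One probe at 6 h correlated with another probe of the same gene at 12 h with r = 0.415 over 5340 genes. For the same probe r was 0.695. Probes of a gene were not checked for shared sequence, so effects that such probes have in common stay open as the whole cause. Probe-specific effects are part of the cause, since deviations of probes from their gene's mean correlated between arrays with r = 0.547. This may reflect sequence-dependent dye effects or clones assigned to a wrong gene. Differences in level between the print blocks do not account for the correlation, which was 0.664 after each block was centred. The block medians had an SD of only 0.15 on each array, against 1.11 and 1.29 over all spots. Centring could therefore change little, and position within a block was not examined. A dye bias that also acts on genes of other cell types stays open: 75 marker genes of other cell types correlated with r = 0.613 (95% bootstrap interval 0.449 to 0.744), and the dyes were not swapped; a shear response shared by both times is likewise untested.

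The third pattern is that 3761 genes passed 2-fold at 12 h against 2592 at 6 h, a ratio of 1.45. Differences in level between the print blocks do not account for the excess, since the ratio was 1.44 after block centring. Gradients within blocks were not examined. Wider scatter of the 12 h array goes with the values and may account for part or all of the excess. The SD between probes of a gene was 1.16 times larger at 12 h. Probe scatter alone gave 654 higher and 661 lower genes in simulated data at 12 h, against 432 and 469 at 6 h. In number of genes this simulated rise was smaller than the excess seen, but in proportion it was about as large. The simulated genes hold no other differences, so the share of the excess due to scatter cannot be told. The ratio was 1.03 with both arrays scaled to one median absolute deviation, a value that such scaling largely sets and that does not tell scatter from a larger response. Which side holds the excess depends on centring, with 641 and 1558 higher against 1951 and 2203 lower genes after centring and 246 and 742 against 2901 and 3763 without it, and no biological explanation was tested.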

How the results depend on the processing

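With 1 array per time point no replicate could be left out. No paired analysis was possible because each group held 1 array. Print-block centring was added after the data were seen, and the other alternatives were planned. In the order of genes higher at 6 h, lower at 6 h, higher at 12 h, lower at 12 h, higher at both and lower at both, the main 2-fold counts were 641, 1951, 1558, 2203, 446 and 1008. They were 1888, 3235, 2618, 3550, 1423 and 2109 at 1.5-fold, and 135, 895, 616, 1046, 57 and 305 at 3-fold. With 2 or more probes per gene they were 347, 672, 970, 925, 273 and 392 (5396 of 10348 genes at 6 h and 5579 of 10733 at 12 h), and the correlation between arrays was 0.766 in place of 0.662, for which the cause was not tested. The Spearman correlation was 0.737. Values as deposited gave 246 and 742 higher genes, 3763 lower genes at 12 h, and 112 higher and 2016 lower at both times; a constant subtracted from each array is the cause. Using the mean of probes, genes on both arrays only, probes with several symbols, arrays scaled to one median absolute deviation or centred print blocks moved none of these counts by more than 1.5 times. Among genes with 2 or more probes, 34.1% of those past 2-fold were higher at 6 h and 51.2% at 12 h, against 24.7% and 41.4% over all genes. Of the list medians, 404 kept within the bootstrap interval over members and 30 did not, 25 of these without centring. The TGF-beta and BMP list lay at percentile 1.12 at 6 h, and at 3.69 with the mean of probes; at 12 h it lay at 3.10, at 0.70 with 2 or more probes per gene and at 17.9 with print blocks centred. The unfolded protein response list lay at percentile 97.8 and 97.515, and within 95% of random lists with the mean of probes (96.1 and 93.3), with 2 or more probes (97.1 and 94.6) and with several symbols kept (96.0 and 97.1); at 12 h also over genes on both arrays (97.4). Epithelial markers at 6 h lay at percentile 6.98, and at 0.36 with the mean of probes. With 2 or more probes leukocyte markers at 6 h lay at 0.70 and the interferon list at 99.2, which lay at 82.2 with several symbols kept. Inflammatory genes at 6 h lay at 97.22, at 97.52 with several symbols kept and at 69.8 with 2 or more probes. Growth factors at 6 h lay at 6.97, and at 37.8 with 2 or more probes. Matrix glycoproteins at 6 h had a median of 0.04, and 0.42 with 2 or more probes. Medians also had the opposite sign with 2 or more probes for metalloproteinases (0.07), apoptosis and p53 targets (0.05) and muscle markers (-0.22) at 6 h, and with print blocks centred for Wnt signalling at 12 h (0.09). Among the genes named by the rule, none past 1.5-fold had the opposite sign under any alternative in which it kept a value. Genes named only after their values were seen were not checked in this way. Spot intensity, which sets how far dim spots can be trusted, was not used here.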

Other observations

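Further gene families were examined after the data had been seen, by grouping genes on both arrays that share the letters at the start of their symbol, with at least 15 genes per family. Of 53 such families, 7 stood apart above random lists on both arrays. Mitochondrial ribosomal proteins of the large subunit (Mrpl) had a median of 0.66 at 6 h and 1.01 at 12 h, with 24 and 38 of 47 genes at least 1.5-fold higher and none lower at either time. Those of the small subunit (Mrps) had medians of 0.51 and 0.84 over 25 genes. Genes whose symbols start with Polr, mostly RNA polymerase subunits, had medians of 0.75 and 1.1 over 25 genes, with 14 and 15 higher and 3 lower at each time. Translation initiation factors (Eif) had a median of 0.43 at 6 h, at percentile 99.9, and 0.24 at 12 h, at percentile 90.5, the latter turning negative without centring. The abundant short transcripts had medians of 0.72 at 6 h and 1.61 at 12 h. The Mrpl, Mrps and Eif medians lay below these on both arrays, and the Polr median lay just above at 6 h and below at 12 h. Random lists were matched on neither expression level nor transcript length.

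Zinc finger proteins (Zfp) had medians of -0.27 and -0.66 over 139 genes, at percentile 29.8 at 6 h and below all random lists at 12 h, where 75 were lower and 17 higher. Genes whose symbols start with Usp, mostly deubiquitinases, had medians of -0.35 and -0.64 over 36 genes, at percentiles 4.41 and 0.26. Keratins (Krt) had medians of -0.90 at 6 h, at percentile 0.14, and -0.35 at 12 h, at percentile 24.6. Symbol families are not independent of the fixed lists for ribosomal proteins and respiration, and these values carry no test.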
